A study of Mus musculus with 4 samples.

How the data were processed

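Host bone marrow cells of mice were measured by droplet RNA sequencing with the 10x Chromium 3' kit, version 3. Wild-type CD45.1 mice had received 150000 tumor cells by vein or PBS 3 weeks earlier, and CD45.1+ cells that carried KIT and lacked CD45.2 and lineage markers were sorted. The labels name 4 samples, 2 per group, with no age or batch used here. Per the submitters' processing notes, Cell Ranger 4 and Seurat 4.0.1 were used, with the mm10 assembly. The deposited matrix holds raw UMI counts per gene and cell, without normalization by the authors. The authors' cell table gives, per cell, a group prefix, the total UMI count, the number of genes detected and the coordinates of a UMAP, and these other values were used as deposited. The matrix holds 11764 cells and 13978 gene symbols, and its sums equalled the deposited totals in 100% of cells. It has no symbol starting with Rps or Rpl and 13 mitochondrially encoded genes, and each gene has a UMI in at least 33 cells. The sources used here do not state how genes and cells were filtered or why both groups have 5882 cells. They also do not state how reads on the opposite strand were handled.

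The cells carry no replicate number, so the 2 samples of each group could not be told apart and each group was 1 sample. The prefix of the treated cells was taken to mean the tumor environment. Several tests chosen before the data were examined therefore could not be run. These were the edgeR quasi-likelihood and DESeq2 Wald tests, camera and fry, the test of class shares, limma on logit shares, the test of an interaction between class and group, leaving out each sample, and the replicate number as a block. Shares of cells per cycle phase were not made, because no phase label was given. The gene lists, the lists of markers, the normalization and the comparisons were chosen before the data were examined. The clusters, the intervals and the random lists were chosen after.

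The PBS control had 68391214 UMIs (3070 to 48408 per cell, median 10189) and the B-ALL environment 76059014 (357 to 56671 per cell, median 10458). In the B-ALL environment 190 cells (3.23%) had fewer than 3070 UMIs, and no control cell did. Mitochondrially encoded genes were 3.56% of control UMIs and 5.14% of those of the B-ALL environment. The planned clustering of both groups together (scanpy 1.11.5, igraph 0.11.9, 10000 counts per cell, 2000 variable genes, 30 components, 15 neighbours, resolution 1) gave 21 clusters, of which 17 were over 90% from 1 group. After this was seen, cells were clustered by the Leiden method on the authors' UMAP (30 neighbours, resolution 0.3). On that map, 43.6% of the 50 nearest neighbours of control cells and 56.2% of those of B-ALL environment cells came from the B-ALL environment. Other clusterings were finer clusters of the map (resolution 0.6), each group alone, and values centred within each group without 625 genes whose log2 values differed by over 0.5. A cluster was named for the marker list with the highest mean log2 enrichment, if that was at least 0.5 with at least 3 markers detected in 10% of cells, with 10 CPM added, and if its 10 leading genes held at least as many markers of that list as of any other. A cluster of low depth with no such leading marker stayed unnamed. Scrublet, run in scanpy, called 6 control cells and 3 cells of the B-ALL environment, so it found almost none, and no cell was removed. An alternative left out the highest 5% of its scores.

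UMIs were summed per class and group and scaled by TMM (edgeR 4.0.16, R 4.3.3), and levels are given as CPM, UMIs scaled to a common library total. Genes were filtered with filterByExpr. Log2 folds are those of the B-ALL environment over the PBS control, with exact 95% conditional intervals (scipy 1.17.1), and shares have exact Clopper-Pearson intervals. Intervals and floors cover counting error only. The floor was 3 UMIs for the group. A group at 0 gives a bound against it, and a group at 1 to 3 UMIs a ratio with its interval. A list with at least 5 tested members was placed by its median among 10000 random lists drawn, for each member, from 100 genes on each side in expression, with seed 1. The r between the folds of HSC-like and monocyte progenitor-like cells, the largest other class, was resampled over genes. The 8 classes with at least 30 cells in both groups were compared. Other software was python 3.11.15, numpy 2.4.6, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, scikit-image 0.26.0, matplotlib 3.10.9 and DESeq2 1.42.0, the last for size factors only.

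The rule for named genes had asked for an adjusted p, which does not exist here. In its place, genes with a mean of at least 10 CPM were named: the 10 highest and 10 lowest folds over all cells and in HSC-like cells, the 3 highest and 3 lowest in other classes, up to 4 members of each list by size of fold, and Ptprc, Kit and Ly6a. The lists were 24 pathway lists with genes in the matrix and lists of markers of blood, immune and stromal cells. The list of cytosolic ribosomal proteins had 0 genes in the matrix and the eosinophil markers 2, too few for a median. Ebf1, Pax5 and genes of the Y chromosome were not in the matrix, so they gave no value. Genes were placed on mm10 with GENCODE annotation, in which 13805 symbols were found.

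The steps after scaling were tested on simulated data, in which counts were drawn from Poisson distributions at each gene's pooled proportion and the real library totals, and 200 genes of at least 10 CPM were given known folds. For log2 folds of 1 or 2 either way, median estimates lay within 0.1 of the truth. The intervals held the truth for 90% to 100% of the 50 genes of each size. A bound of over 90% for each size had been set first, and 1 size reached only 90%. The criterion was changed after that failure to over 92% of all changed genes together. A list of 20 raised genes lay at percentile 100, and 6% and 2% of 100 unchanged lists lay outside the range over all cells and in HSC-like cells. The simulated genes were independent and had no library effect. Neither the coverage nor these percentages therefore show how often lists of genes regulated together leave the range in real libraries. Alternatives were DESeq2 size factors, no filter on low counts, sums thinned to the lower total, equal cell numbers, equal class composition, HSC-like cells of middle depth (5223 to 10188 UMIs), cells with at least 3070 UMIs or at least 10189, TMM of cell numbers, no cells rich in globin or Igkc, no high doublet scores, and the other clusterings. The clusterings, the minimum of 3070 UMIs, the removal of rich cells and the doublet scores were chosen after seeing the data.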

Results

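Blood progenitors of the host were profiled in mice carrying B-cell acute lymphoblastic leukemia (B-ALL) and in mice without it, which addresses how normal hematopoiesis differs inside a leukemic marrow. Wild-type mice of the CD45.1 type received 150000 tumor cells by vein from a diseased lymph node of a CD45.2 mouse that had lost 1 copy each of Ebf1 and Pax5, transcription factors of the B lineage. Control mice received phosphate-buffered saline (PBS). After 3 weeks, marrow cells of the host that carried KIT, the receptor of stem cell factor, and lacked lineage markers were sorted for droplet RNA sequencing from the 3' end. The deposited matrix held 5882 cells per group. The PBS control had 68391214 unique molecular identifiers (UMIs), with a median of 10189 per cell, and the B-ALL environment had 76059014, with a median of 10458. The labels name 2 samples per group, but the cells carry no replicate number, so each group counted as 1 sample. No difference between groups could be set against a spread between mice, no p-value is given, and every interval is a 95% interval for counting error only.

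HSC-like cells, named by markers of hematopoietic stem cells such as Mecom, Hlf and Fgd5, were 5.51% of control cells (324 cells, exact binomial interval 4.94 to 6.12%) and 19.0% of cells in the B-ALL environment (1117 cells, 18.0 to 20.02%). The ratio of these shares was 3.45 (3.04 to 3.91). Megakaryocyte-like cells had shares of 8.38% and 15.2%, a ratio of 1.82 (1.62 to 2.03), and multipotent progenitor-like cells of 8.91% and 13.3%, a ratio of 1.49 (1.33 to 1.67), which was 1.16 (0.9504 to 1.42), within counting error, among cells with at least 10189 UMIs. Erythroid-like cells had the lowest ratio, 0.239 (0.204 to 0.279), with 14.4% of control cells and 3.45% of cells in the B-ALL environment. Monocyte progenitor-like cells were 17.8% and 12.1%, a ratio of 0.677 (0.615 to 0.746). Neutrophil progenitor-like cells were 6.77% and 5.03%, a ratio of 0.744 (0.638 to 0.867), which was 0.953 (0.840 to 1.08), within counting error, with each group clustered alone. Basophil and mast cell-like cells were 3.94% and 2.70%, a ratio of 0.685 (0.557 to 0.842). Among cells with at least 10189 UMIs their ratio was 1.02 (0.696 to 1.51), within counting error. This cut also selects by depth, which differed between the groups within classes. Median UMIs per cell were 8747 in the control and 7441.5 in the B-ALL environment for multipotent progenitor-like cells. For basophil and mast cell-like cells they were 6931 and 8473. Lymphoid-primed-like cells, at 5.36% and 4.83%, had a ratio of 0.902 (0.765 to 1.06), a difference within counting error. With clusters of centred values the ratio was 0.765 (0.656 to 0.890), a difference beyond counting error. With each group clustered alone it was 9.58 (7.19 to 13.002), but on 52 control cells, because the naming rule left unnamed a cluster of 546 control cells whose highest enrichment, 1.23, was for lymphoid-primed markers and whose leading genes included Dntt. This ratio therefore depends on the naming rule. The multipotent progenitor-like class was found in both groups with the map clusters alone. With finer clusters or centred values no cell was given that name, and with each group clustered alone 332 control cells and no cell of the B-ALL environment were, although 416 cells of the B-ALL environment lay in an unnamed cluster with its highest enrichment, 0.817, for these markers.

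Because genes that define these classes differed between the groups, cells were also clustered on values centred within each group and without 625 differing genes. HSC-like cells were then 2.16% of control cells and 18.9% of cells in the B-ALL environment, a ratio of 8.75 (7.28 to 10.6). This ratio rested on 127 control cells. A cluster of 377 control and 478 B-ALL environment cells stayed unnamed in this clustering. The HSC markers Hlf and Gcnt2 were among its leading genes, while its highest enrichment, 0.973, was for multipotent progenitor markers. The erythroid-like ratio was 0.189 (0.166 to 0.215) and the megakaryocyte-like ratio 1.69 (1.54 to 1.84), while the basophil and mast cell-like ratio was 1.10 (0.945 to 1.28). That class then joined a cluster with an enrichment of 3.14, which held 178 control and 115 B-ALL environment cells, with a cluster at 0.661, led by mitotic genes such as Ube2c and Cenpf, which held 146 and 242, so the value above 1 came from the second cluster alone. With each group clustered alone the HSC-like ratio was 2.01 (1.73 to 2.33), which depended on the naming rule. The control cells named HSC-like in it formed 1 cluster with enrichments of 0.7314 for HSC and 0.7306 for multipotent progenitor markers, while clusters of 546 control and 649 B-ALL environment cells with HSC enrichments of 1.18 and 1.09 stayed unnamed. Among cells with at least 10189 UMIs the megakaryocyte-like ratio was 4.77. Megakaryocyte-like cells had a median of 7561 UMIs in the control and 12752 in the B-ALL environment. Shares describe cells that passed a KIT sort, and Kit transcripts were lower in the B-ALL environment, with a log2 fold of -0.84 (-0.87 to -0.82) over all cells.

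**Figure D1:**
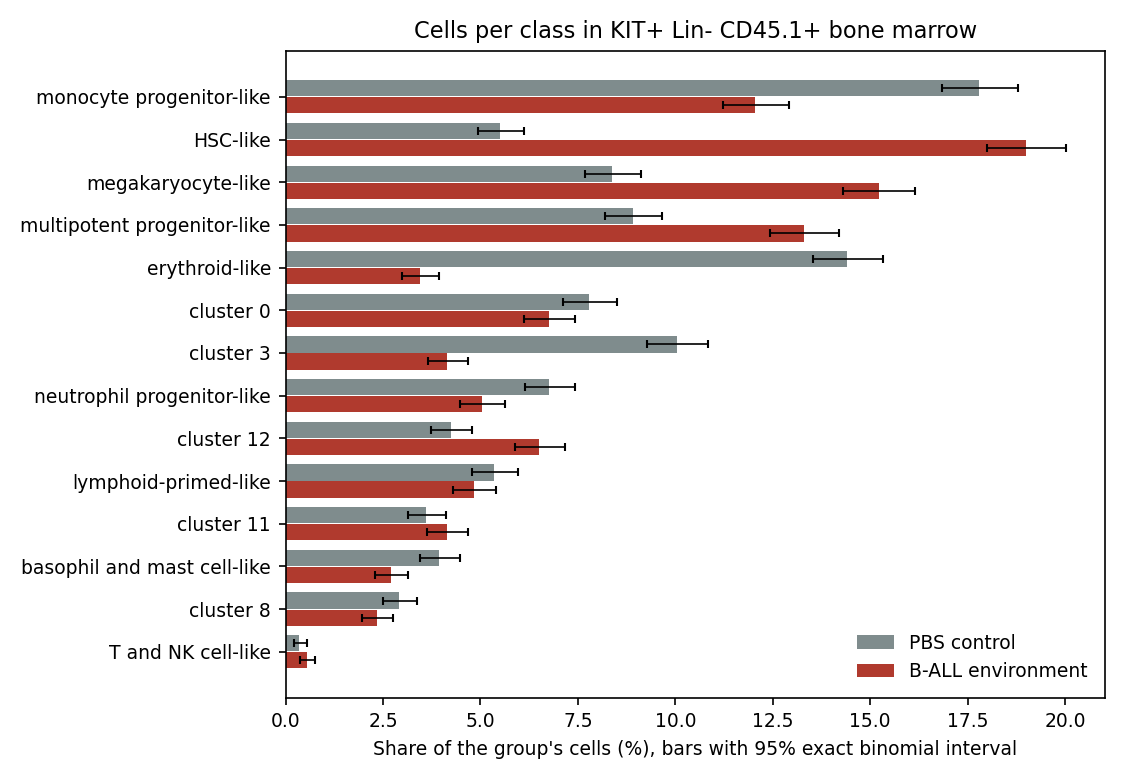
Share of each group's 5882 cells in every class or unnamed cluster, in percent, with bars for the PBS control and the B-ALL environment and 95% exact binomial intervals for counting error. The HSC-like bar stands at 5.51% in the control and 19.0% in the B-ALL environment, and the erythroid-like bar at 14.4% and 3.45%.

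Unnamed clusters held the rest of the cells. Cluster 3, led by St8sia6 and Mfsd2b among other genes, was 10.0% of control cells and 4.15% of cells in the B-ALL environment, a ratio of 0.414 (0.355 to 0.481). Cluster 12, led by Hlf and Vldlr, had a ratio of 1.54 (1.31 to 1.81), and cluster 0, led by Ccl9 and Cxcr2, a ratio of 0.867 (0.756 to 0.994). Cluster 11, led by Apoe and with Gata2 among its first genes, had a ratio of 1.15 (0.949 to 1.38). Cluster 8, led by globin and immunoglobulin genes, had a ratio of 0.807 (0.640 to 1.02). Globin or Igkc exceeded 1% of UMIs in only 6 of its 138 B-ALL environment cells and 1 of its 171 control cells. T and NK cell-like cells numbered 21 in the control and 32 in the B-ALL environment. Within the HSC-like class, cluster 5, which was led by immune genes such as Iigp1, Ifi44 and Ifit1 beside Hlf and Mecom, held 62.0% of control and 60.7% of B-ALL environment cells.

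Over all cells, Socs2 and Cish, which encode feedback inhibitors of cytokine signaling, were among the 10 genes with the highest folds in the B-ALL environment. Socs2, a suppressor of cytokine signaling, had a scaled level of 1.87 CPM in the control and 59.8 in the B-ALL environment, a log2 fold of 5.002 (4.75 to 5.27). Cish, a related feedback inhibitor, had a log2 fold of 3.54 (3.37 to 3.72). Podxl, which encodes the sialomucin podocalyxin, had a log2 fold of 5.31 (4.85 to 5.81), Timp3, a metalloproteinase inhibitor, 3.41 (3.25 to 3.58), and the T-cell receptor gamma constant gene Tcrg-C1 3.98 (3.67 to 4.31). Erythroid genes were lower: Ermap, an erythroid membrane protein, had a log2 fold of -3.42 (-3.53 to -3.30) and Tspo2, another erythroid gene, -2.89 (-3.01 to -2.77).

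The remaining genes with the 10 lowest folds were Sphk1 at -3.58 (-3.85 to -3.32), Atp1b2 at -3.34, Trib2 at -3.29, Gm11505 at -3.25, Slc25a21 at -3.24, Prss50 at -3.20, Col5a1 at -2.88 and Rec114 at -2.84. With the same number of cells of every class drawn from both groups, the log2 folds of Sphk1, Ermap and Slc25a21 were -1.50, -1.62 and -1.33. The immunoglobulin light chain gene Igkc had the highest log2 fold, 10.97 (10.09 to 12.03), and 22839 of its 22912 UMIs in the B-ALL environment lay in 5 cells of cluster 8. The globin genes Hba-a2 and Hba-a1 are near-identical copies, as are Hbb-bs and Hbb-bt. Counting could have split reads differently within each pair. In that order their log2 folds were 4.27, 4.13, 3.45 and 3.38. These values were carried by few cells: globin or Igkc exceeded 1% of UMIs in 15 cells of the B-ALL environment and 3 control cells. Without those cells the folds were -0.84 for Hba-a2, -0.57 for Hba-a1, -1.03 for Hbb-bs, 1.96 for Hbb-bt and 2.74 for Igkc.

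Stem cell genes and inflammatory response genes stood higher together over all cells. All 15 HSC markers were higher in the B-ALL environment, 13 of them by more than 1.5-fold, with a median log2 fold of 1.59. Among them, Esam, an adhesion molecule, had a log2 fold of 2.57, Ly6a, which encodes the surface antigen SCA-1, 2.56, and Mecom, a stem cell transcription factor, 1.59. Of 34 quiescence genes 24 were higher, with a median of 0.70, Mycn at 2.66 and Id1 at 1.79. Of 26 genes of the TNF and NF-kB response 23 were higher, with a median of 0.61, including Bcl3 at 2.20 and the NF-kB inhibitor Nfkbia at 1.02, while Tnfaip2 was at -1.29. Of 20 genes of the IL-6 and STAT3 response 13 were higher, with a median of 0.52 and Socs3 at 2.93. Of 24 cholesterol synthesis genes 23 were higher, with a median of 0.45, including Msmo1 at 0.85 and Idi1 at 0.68.

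Lists were placed by their median among 10000 random lists of the same size matched on expression. Of 24 pathway lists, 13 lay above the central 95% of those lists, called the random range here, and 3 below it. Besides those named, the lists above were immediate early and dissociation genes at 0.37, mitochondrially encoded genes at 0.34, interferon gamma response at 0.33, inflammatory receptors and surface genes of stem cells at 0.22, p53 targets and apoptosis at 0.21, TGF-beta response at 0.20, glycolysis at 0.16, niche retention and homing at 0.14 and G2/M phase genes at 0.09. Serpina3g, a protease inhibitor in the interferon gamma list, had a log2 fold of 3.13 (3.08 to 3.19), and Socs1 of 2.42. The lists below were emergency granulopoiesis with myeloid growth factors at -0.31, haem synthesis and iron at -0.29 and nuclear genes of oxidative phosphorylation at -0.26, where 73 of 77 genes were lower. Alas1, an enzyme of haem synthesis, was at -0.79, and Cox7b, a subunit of cytochrome oxidase, at -0.66. Within the random range were MHC class II presentation at 0.25, type I interferon response at 0.14, heat shock proteins at 0.08, S phase genes at 0.03, unfolded protein response at 0.0058, MYC targets with ribosome biogenesis at -0.02, hypoxia response at -0.12 and antioxidant response at -0.13.

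With equal numbers of cells of every class, interferon gamma response had a median of 0.07, haem synthesis of -0.04, TGF-beta response of 0.09 and the inflammatory receptor list of 0.11, all within the random range, and HSC markers still had a median of 0.75. In that setting 3 lists of pathways or markers that had lain within the range came to lie outside it. Markers of other lineages were lower over all cells: erythroid markers had a median of -0.88, neutrophil progenitor markers of -0.84, basophil and mast cell markers of -0.76 and monocyte progenitor markers of -0.34. Dendritic cell markers had a median of 0.89, megakaryocyte markers of 0.51 and multipotent progenitor markers of 0.16. With equal class numbers the erythroid median was -0.03, the monocyte median -0.10 and the megakaryocyte median 0.04, while the multipotent median turned to -0.02. Stromal and endothelial markers, of which 5 were measured, had a median of 1.16, and 0.43 with equal class numbers, within the range. Lymphoid-primed progenitor markers, at -0.12, B cell markers, at 0.49, T and NK cell markers, at 0.46, and macrophage markers, at 0.35, lay within the range. Xist, which is transcribed from an inactive X chromosome, was at 2432 and 2320 CPM.

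**Figure D2:**
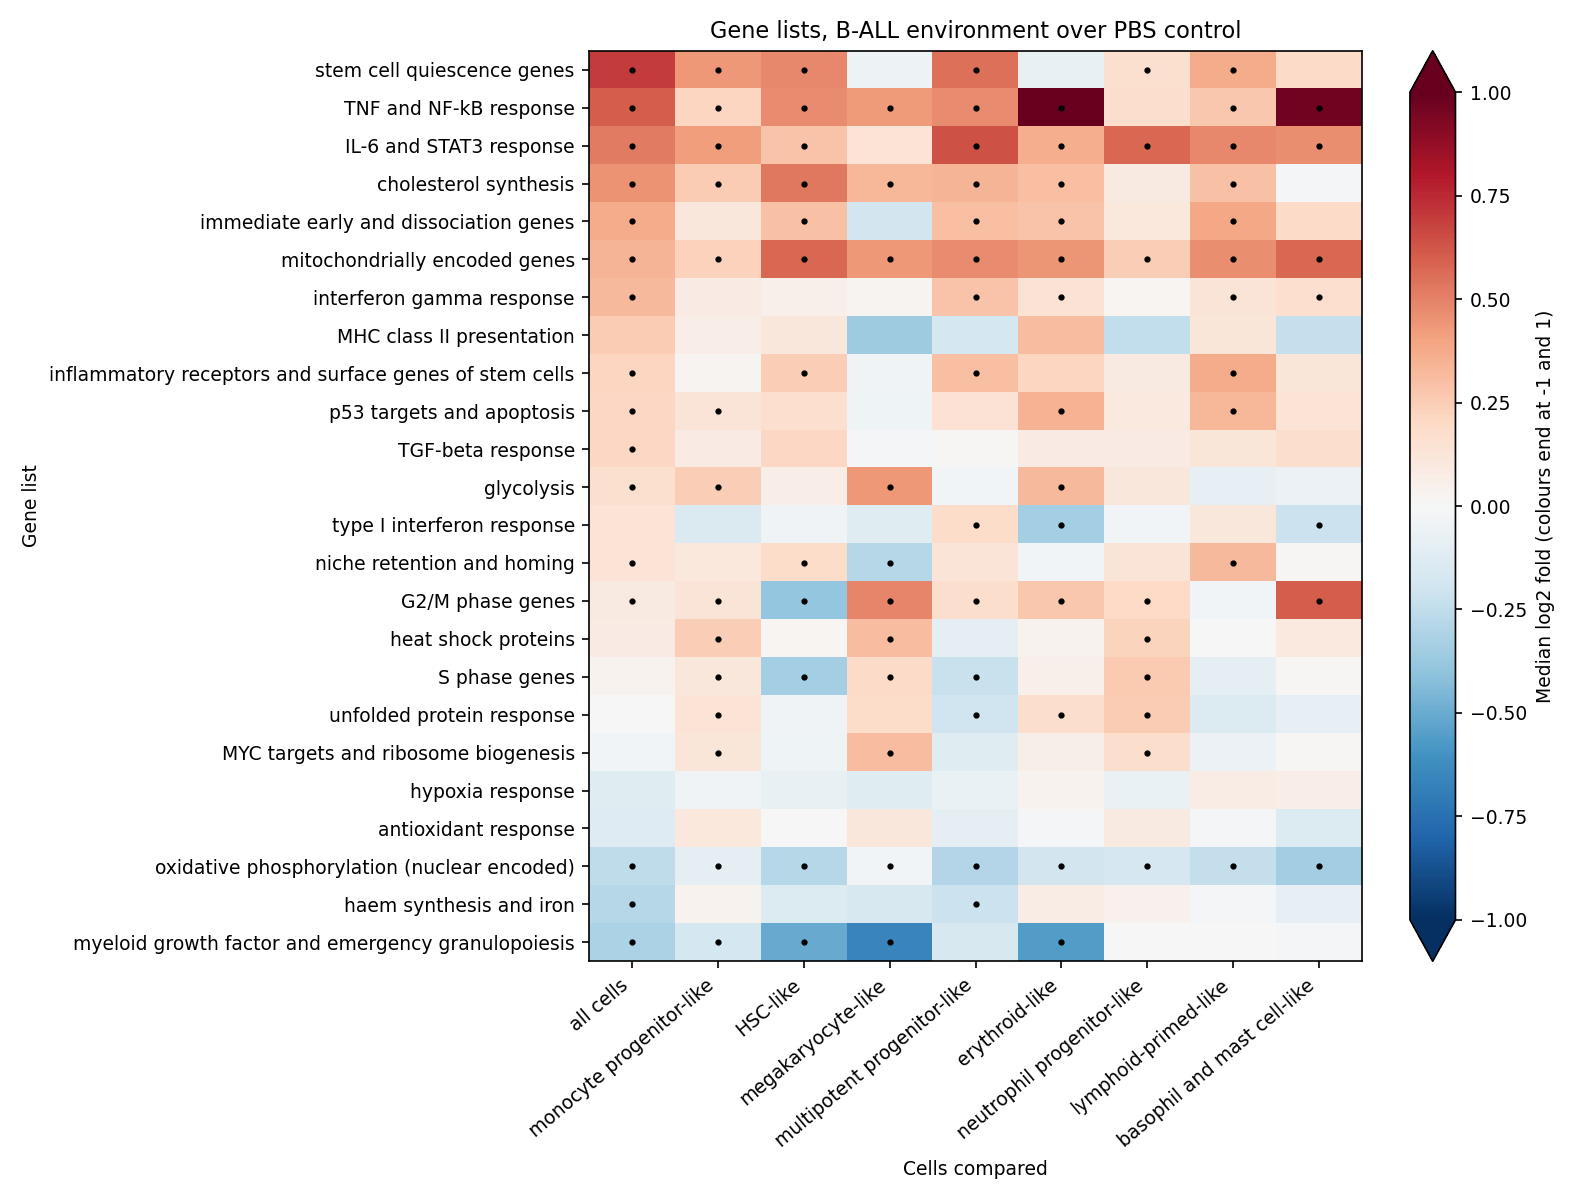
Median log2 fold of 24 pathway lists (down the side) over all cells and in 8 classes (across), B-ALL environment over PBS control, with colours ending at -1 and 1 and a dot where the median lay outside the central 95% of 10000 matched random lists. Nuclear genes of oxidative phosphorylation were below the range in all 8 classes, and mitochondrially encoded genes were above it in all 8. In megakaryocyte-like cells the oxidative phosphorylation median was only -0.03, with 35 of 76 genes higher.

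In HSC-like cells, HSC markers and the cytokine feedback genes Socs2 and Cish were higher in the B-ALL environment. Socs2 had 10.2 CPM in control HSC-like cells and 260 in those of the B-ALL environment, a log2 fold of 4.68 (4.12 to 5.29), and Cish 13.7 and 166, a log2 fold of 3.60 (3.12 to 4.13). Podxl had a log2 fold of 3.85 (2.91 to 4.99) and Ikzf4, a zinc finger transcription factor, of 4.39 (3.15 to 6.02). Ncam2, a neural adhesion molecule, had no UMI in control HSC-like cells and 281 in the B-ALL environment, which makes it at least 25.4-fold higher against a floor of 3 UMIs for the group. Genes with 1 to 3 control UMIs were Enah, a regulator of actin, with 2 and 339 UMIs (45.9-fold, interval 12.6 to 381), Hes1, a Notch target, with 2 and 184 (24.9-fold, 6.80 to 207), and Clu, which encodes clusterin, with 3 and 252 (22.8-fold, 7.70 to 111). The globin genes Hba-a2, Hba-a1 and Hbb-bs had log2 folds of 5.63, 5.003 and 4.38, and -0.07, -0.83 and -0.81 without the 2 HSC-like cells rich in globin.

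Of the 15 HSC markers, 14 were higher within this class, with a median log2 fold of 1.36. Fgd5 had a log2 fold of 2.81 (2.07 to 3.66), Esam of 1.75, Hoxb5 of 1.72, Slamf1 of 1.70 and Ly6a of 1.36 (1.15 to 1.57). These genes also served to name the class, and with clusters of centred values the median was 0.33, still above the random range. Kit was lower in HSC-like cells of the B-ALL environment, with 537 CPM in the control and 255 in the B-ALL environment, a log2 fold of -1.07 (-1.17 to -0.98). Cd34, a progenitor antigen, was at -1.01 (-1.11 to -0.91) and Cd48 at -0.82, and Ptprc, which encodes CD45, at 0.23 (0.09 to 0.37). Mycn, at 2.41 (2.16 to 2.67), and the differentiation inhibitors Id1, at 2.84, and Id2, at 2.57, were higher. Cd74, the invariant chain of MHC class II, was at 2.82 (2.22 to 3.49), Serpina3g at 1.78 and Socs1 at 2.08.

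Among pathway lists in HSC-like cells, 8 lay above the random range and 4 below. Mitochondrially encoded genes had a median of 0.58, with mt-Co3 at 1.05, cholesterol synthesis of 0.53, with Msmo1 at 0.78, and quiescence genes of 0.48, with 26 of 34 higher. TNF and NF-kB response had a median of 0.47, with Bcl3 at 1.65 and Nfkb2 at 1.10, IL-6 and STAT3 response of 0.29, immediate early and dissociation genes of 0.29, inflammatory receptors of 0.25 and niche retention genes of 0.18. Genes of the cell cycle were lower: 38 of 42 S phase genes, with a median of -0.34 and Cdc6, a licensing factor of replication, at -0.66, and 53 of 54 G2/M genes, with a median of -0.39 and Nek2, a mitotic kinase, at -0.94. Nuclear genes of oxidative phosphorylation had a median of -0.28, with 71 of 75 lower, and emergency granulopoiesis genes of -0.50, with the myeloid factor Cebpa at -2.36. Type I interferon response, at -0.03, and interferon gamma response, at 0.05, lay within the range.

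Several of these values depended on where the class boundary lay. With clusters of centred values, S phase genes turned to 0.23, above the range, quiescence genes to -0.07 and immediate early genes to -0.10, and the medians of TNF and NF-kB response, at 0.06, IL-6 and STAT3 response, at 0.15, nuclear oxidative phosphorylation, at -0.03, emergency granulopoiesis, at -0.19, and inflammatory receptors, at 0.14, lay within the range. Interferon gamma response, at -0.21, then lay below it and glycolysis, at 0.20, above it. Niche retention genes, at 0.08, lay within it when each group was clustered alone, while type I interferon response, at 0.79, and interferon gamma response, at 0.64, then lay above. In that setting, where the control cells were those of the cluster with nearly equal HSC and multipotent enrichment, S phase genes were at -1.78, MYC targets at -0.61 and haem synthesis at -0.46, below the range, and TGF-beta response was at 0.54, above it. Mitochondrially encoded genes, cholesterol synthesis and G2/M genes stayed outside the range on the same side in both. The other lists within the range were TGF-beta response at 0.21, p53 targets at 0.16, MHC class II presentation at 0.12, glycolysis at 0.07, heat shock proteins at 0.02, antioxidant response at -0.00049, unfolded protein response at -0.04, MYC targets at -0.05, hypoxia response at -0.07 and haem synthesis at -0.14.

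Transcripts of several lineages were lower in HSC-like cells of the B-ALL environment. Mpo, which encodes myeloperoxidase, had 433 CPM in the control and 36.2 in the B-ALL environment, a log2 fold of -3.58 (-3.76 to -3.41). Ctsg and Elane, which encode granule proteases, were at -4.31 (-4.61 to -4.03) and -3.36 (-3.70 to -3.03), Cpa3, a mast cell protease, at -4.60 (-5.15 to -4.09), and Car1, an erythroid carbonic anhydrase, at -4.56 (-5.69 to -3.59). Ms4a3 was at -3.02, Clec12a at -3.57, Atp8b4 at -3.70, BC035044 at -3.04 and the long RNA AY036118 at -2.99. Neutrophil progenitor markers had a median of -2.30, basophil and mast cell markers of -3.68, lymphoid-primed markers of -0.95, monocyte progenitor markers of -0.86 and megakaryocyte markers of -0.54. Erythroid markers went both ways, with 6 of 13 higher, and had a median of -0.31, which turned to 0.10 with finer clusters. Dendritic cell markers were at 0.71. With clusters of centred values the dendritic and megakaryocyte medians were 0.05 and -0.19, within the range. With the map clusters, multipotent progenitor, macrophage and stromal markers, at -0.13, 0.57 and 0.61, lay within the range.

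Ctsg was detected in more control cells of classes outside the neutrophil lineage. A Ctsg UMI was found in 66.5% of control megakaryocyte-like cells and 9.72% of those of the B-ALL environment, in 71.7% and 14.3% of erythroid-like cells, and in 70.7% and 6.71% of HSC-like cells. Median UMIs per cell were 7561 and 12752 in the megakaryocyte-like class and 7256.5 and 7293 in the HSC-like class. With cells thinned to 3070 UMIs, which left out 190 cells of the B-ALL environment, the shares with Ctsg were 41.0% and 2.25% in megakaryocyte-like and 45.7% and 3.36% in HSC-like cells.

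**Figure D3:**
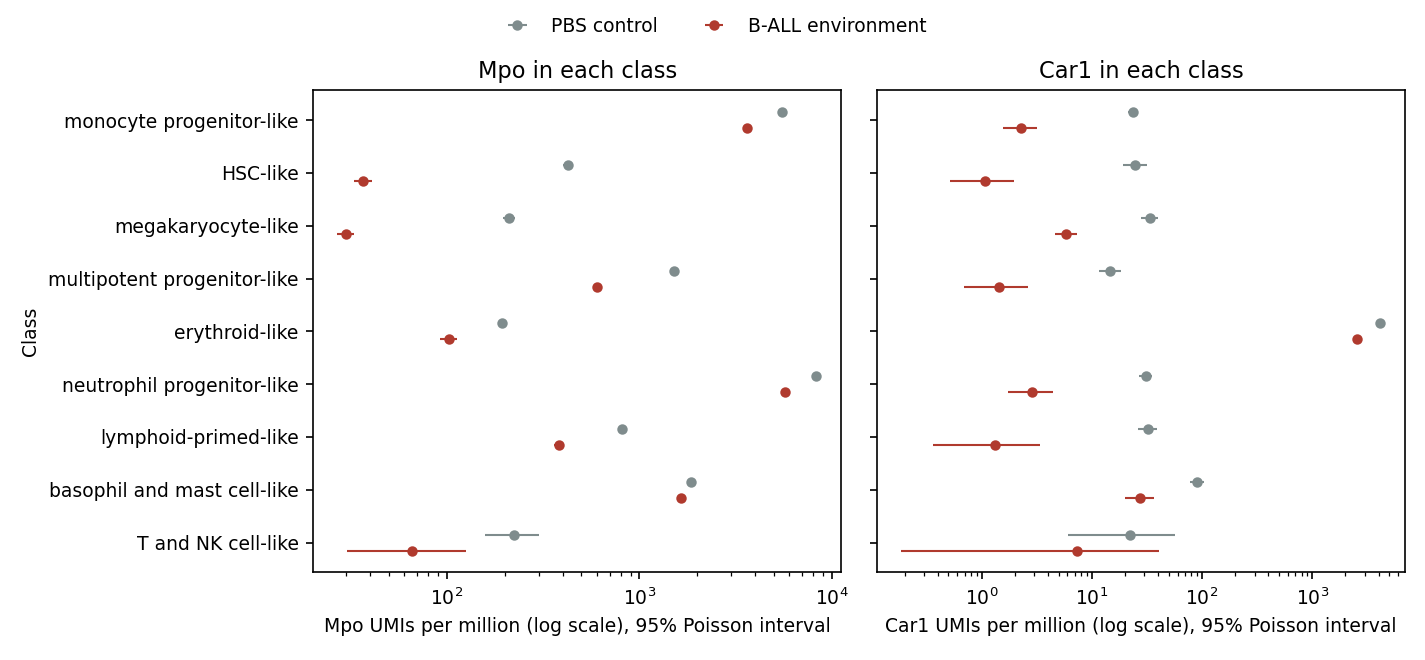
UMIs of Mpo (left) and Car1 (right) in each class, as unscaled CPM on log axes, with points for the PBS control and the B-ALL environment and 95% Poisson intervals for counting error. Control cells of every class shown carried Car1 at 14.6 CPM or more. In HSC-like cells Mpo stood at 428 in the control and 36.5 in the B-ALL environment before scaling.

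HSC-like cells and monocyte progenitor-like cells, the largest other class, differed from their controls in part alike. Across 7987 genes the log2 folds of both classes had a Pearson r of 0.50 (0.465 to 0.538 over resampled genes, which are not independent replicates), and 63.0% of genes had the same sign. Both sets of folds come from the same pair of libraries, so effects of a library are shared by them. All 42 S phase genes and 53 of 54 G2/M genes had a lower fold in HSC-like cells, with median differences of -0.46 and -0.51, below the random range, and the emergency granulopoiesis list and niche retention genes were also below it at -0.35 and -0.22. Of 13 HSC markers 8 had a lower fold in HSC-like than in monocyte progenitor-like cells, with a median difference of -0.28, below the range, and their median in monocyte progenitor-like cells alone was 0.89, but 0.41 without the highest doublet scores, 0.46 with each group clustered alone and 1.59 with finer clusters. Differences for neutrophil, monocyte, lymphoid-primed, megakaryocyte and basophil markers, at -1.26, -0.59, -0.97, -0.38 and -3.06, were below it as well. All 13 mitochondrially encoded genes had a higher fold in HSC-like cells, with a median difference of 0.37, as did 18 of 23 cholesterol synthesis genes, with 0.28, both above the range, where erythroid markers, at 0.36, and inflammatory receptors, at 0.19, also lay. With clusters of centred values S phase genes turned, with medians of 0.23 in HSC-like and 0.047 in monocyte progenitor-like cells, while G2/M genes were at -0.31 and 0.09. The r was 0.41 with clusters of centred values and 0.20 with each group clustered alone.

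In monocyte progenitor-like cells, Ifitm1, an interferon-induced membrane protein, had 147 CPM in the control and 1149 in the B-ALL environment, which is 7.80-fold higher (7.48 to 8.15). Serpina3g was 4.23-fold higher (3.68 to 4.87) and Wfdc17 4.17-fold (3.56 to 4.90). Car1 was 10.3-fold lower (7.24 to 15.2), the histone gene Hist1h4k 8.23-fold lower (5.70 to 12.2) and Gm11505 6.96-fold lower (5.37 to 9.15). With cells thinned to 3070 UMIs, Car1 was detected in 3.82% of control and 0.424% of B-ALL environment cells of this class. Free RNA as a cause of lower Car1 was not tested outside the HSC-like class. In neutrophil progenitor-like cells, Ifitm1 was 10.8-fold higher (9.89 to 11.8), Serpina3g 5.23-fold (4.37 to 6.30) and the small GTPase gene Rhoj 4.28-fold (3.14 to 5.92), while Car1 was 10.8-fold lower, Hist1h4c 6.87-fold lower and Gm11505 5.99-fold lower. Counts of Hist1h4c and Hist1h4k are uncertain, because histone genes are near-identical copies.

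In multipotent progenitor-like cells, S100a4, a calcium-binding protein, was 14.5-fold higher (9.53 to 23.1) and Npdc1 16.1-fold (7.19 to 44.5), and Socs2 had 3 control UMIs and 537 in the B-ALL environment (129-fold, 43.8 to 626). The cyclin gene Ccnd1 was 12.4-fold lower (7.87 to 20.5), the protease inhibitor Slpi 11.7-fold lower (6.82 to 21.5) and Hist1h4a 7.57-fold lower (5.49 to 10.6). In megakaryocyte-like cells, Slfn2 was 31.5-fold higher (19.0 to 56.5), Col18a1, a collagen chain, 23.8-fold (12.0 to 55.3), and Enah had 2 control UMIs and 374 (59.1-fold, 16.3 to 490). Ctsg was 13.4-fold lower (11.2 to 16.0), Elane 12.3-fold lower (10.0 to 15.3) and the potassium channel gene Kcnc1 11.8-fold lower (7.496 to 19.1). An Elane UMI was found in 55.6% of control and 9.39% of B-ALL environment megakaryocyte-like cells.

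In erythroid-like cells, Tcrg-C1 had 0.866 CPM in the control and 309 in the B-ALL environment, 356-fold higher (198 to 716). Serpina3g was 151-fold higher (113 to 207) and Hbb-bs 108-fold (94.1 to 124), although Hbb-bs rested on few cells, of which 7 in the B-ALL environment were rich in globin. Ccnd1 was 19.8-fold lower (7.64 to 73.1), Tceal3 17.6-fold lower (7.9995 to 48.2) and AY036118 8.01-fold lower (7.09 to 9.09). In lymphoid-primed-like cells, S100a4 was 12.9-fold higher (8.45 to 20.7), 1700003C15Rik 11.7-fold (5.12 to 33.0) and Sema3d, a semaphorin, 7.78-fold (3.72 to 18.8). Thbs1, which encodes thrombospondin, had 84 control UMIs and 3 in the B-ALL environment (27.9-fold lower, 9.22 to 138), Car1 was 24.6-fold lower (9.33 to 92.2) and Hist1h4k 14.9-fold lower (5.54 to 56.6). In basophil and mast cell-like cells, Tnip3, an inhibitor of NF-kB signaling, was 47.6-fold higher (18.2 to 177) and Tesc 13.4-fold (4.91 to 51.4), and Bcl3 had 3 control UMIs and 37 (14.4-fold, 4.56 to 73.1). Hbb-bs was 9.58-fold lower (3.87 to 30.7), Dusp6 8.13-fold lower (3.51 to 23.1) and AY036118 7.44-fold lower (6.33 to 8.80).

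Across the 8 classes, Serpina3g, Ifitm1, Cish, Socs1 and Bcl3 were higher in the B-ALL environment in all 8, and Socs2 and Ly6a in all 7 in which they were tested. Kit was lower in all 8, with log2 folds from -1.23 to -0.18. TNF and NF-kB response and IL-6 and STAT3 response each lay above the random range in 7 classes and within it in 1, where each had its lowest median. Over all 8 classes their medians ran from 0.18 to 1.87 and from 0.14 to 0.64. In monocyte progenitor-like cells the TNF and NF-kB median fell to 0.07, within the range, with clusters of centred values, and the G2/M median to 0.05, within it, with each group clustered alone. Mitochondrially encoded genes lay above the range by their median in all 8 classes, although mt-Nd6 and mt-Atp8 were lower in all 8. Immediate early and dissociation genes, which respond to handling of cells, lay above it in 4. Cholesterol synthesis lay above it in 6 classes. G2/M genes lay above it in 6 classes and below it in 1, the HSC-like class, with medians from -0.39 to 0.60. Interferon gamma response lay above it in 4 classes, and type I interferon response above in 1 and below in 2. HSC markers lay above it in 6 classes, neutrophil progenitor markers below it in 7 and erythroid markers below it in 7. Ptprc was higher in 7 classes and lower in 1, the megakaryocyte-like class, with log2 folds from -0.20 to 0.40.

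Positions are those of the GRCm38 assembly (mm10), from a reference annotation, since the matrix gives gene symbols alone. Socs2 lies on chromosome 10 from 95385362 to 95417180 on the minus strand, Cish on chromosome 9 from 107296026 to 107302784 on the plus strand, Podxl on chromosome 6 from 31519488 to 31563981 on the minus strand, and Serpina3g on chromosome 12 from 104236245 to 104241939 on the plus strand. Kit lies on chromosome 5 from 75574916 to 75656722 on the plus strand, Ly6a on chromosome 15 from 74994877 to 74998031 on the minus strand and Mpo on chromosome 11 from 87793581 to 87804413 on the plus strand. All are annotated as protein-coding.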

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

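All tests in this part were chosen only after the results they concern were seen, except the detection of HSC markers at 1 depth and the antisense genes, whose predictions were written before those results. The antisense prediction was written after Tsix, a member, had been seen.

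Lists of the cell cycle and of lymphoid priming had opposite signs in HSC-like and monocyte progenitor-like cells. S phase genes had a median log2 fold of -0.34 in HSC-like cells and 0.11 in monocyte progenitor-like cells, and G2/M phase genes of -0.39 and 0.13. Lymphoid-primed progenitor markers had a median of -0.95 in HSC-like cells and 0.25 in monocyte progenitor-like cells. With clusters of centred values S phase genes were at 0.23 and 0.047, so their signs were no longer opposite, and with each group clustered alone the lymphoid-primed median in monocyte progenitor-like cells was -0.22. With 1 sample per group these differences were not tested between samples.

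Cluster 8, which was part of the sums over all cells but had no comparison of its own, held a few cells with abundant immunoglobulin or globin transcripts. Globin or Igkc exceeded 1% of UMIs in 6 of its 138 B-ALL environment cells and 1 of its 171 control cells, so its levels rest on few cells. Igkc was at 0 CPM in the control and 21772 CPM in the B-ALL environment, and Hbb-bs at 853.5 and 13970 CPM. Of the Igkc UMIs over all cells of the B-ALL environment, 22839 lay in 5 cells of this cluster. No explanation was tested.

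HSC-like cells had a larger share in the B-ALL environment. Among cells with at least 3070 UMIs the ratio was 3.42 (3.02 to 3.88). This minimum left out only 190 of 5882 cells of the B-ALL environment, too few to account for the larger share whatever their class. The setting could therefore not have come out otherwise, and no conclusion on depth is drawn from it. Outside the erythroid-like class the ratio was 3.06 (2.70 to 3.47), which argues against a loss of erythroid-like cells alone. With each cell thinned to 3070 UMIs, 7.004% of control cells and 25.9% of B-ALL environment cells had UMIs of at least 3 HSC markers other than Ly6a, a ratio of 3.70 (3.31 to 4.14). This ratio leaves placement by other genes open, against the prediction written for it, because the markers were also detected in more cells within classes, with shares of 44.1% and 72.1% in HSC-like and 16.2% and 25.2% in megakaryocyte-like cells. Placement by other genes, higher expression of the markers per cell, a different passage of the KIT gate, a difference between libraries and an effect of the leukemia all remain open, the last 3 because library and group coincide.

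Car1, an erythroid gene, and the neutrophil genes Mpo, Ctsg and Elane were lower in HSC-like cells of the B-ALL environment, while of 13 erythroid markers 6 were higher and 7 lower, with a median that turned to 0.098 with finer clusters. In control HSC-like cells Car1 stood at 0.737 times (0.540 to 0.998) its level in control megakaryocyte-like cells and Elane at 1.03 times (0.886 to 1.20), so free RNA in the control library is a candidate cause for both. Mpo stood at 2.04 times (1.86 to 2.23), which free RNA alone, with a like level in both classes, would not give. Ctsg stood between these at 1.505 times (1.35 to 1.68), and at 1 depth it was detected in 45.7% (40.2 to 51.3%) of control HSC-like and 41.0% (36.6 to 45.5%) of control megakaryocyte-like cells, so free RNA cannot be told apart from transcription in the cells for Ctsg. Free RNA as part of the Mpo difference, and low transcription of these genes in some control HSC-like cells, stay open.

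Tsix, AY036118 and histone transcripts were lower in the B-ALL environment. Genes annotated as antisense lay below the random range in 9 of 9 comparisons, with a median log2 fold of -0.27 over all cells. A different capture of antisense transcripts between the libraries is therefore a candidate cause for Tsix. The shift was small, from -0.47 in megakaryocyte-like to -0.04 in multipotent progenitor-like cells, where 158 of 297 genes were lower. Tsix fell far more, with log2 folds from -2.31 to -1.69 across classes, so a shift of that size alone would not give its fall. Genes annotated as lincRNA, among them AY036118, lay below the range in 4 of 9, so the shift was not confined to genes annotated as antisense in those comparisons. Whether lincRNA genes such as AY036118 lie opposite another transcript was not examined. Histone genes lay below the range in 9 of 9 comparisons, of which 1 was all cells together. S phase genes lay below it in 2 of 9, the HSC-like and multipotent progenitor-like classes, with medians of -0.34 and -0.22. Outside those 2 classes this argues against fewer cells in S phase as the cause for the histone genes. Within them, fewer cells in S phase as part of the histone fall stays open. Strand handling was not given in the sources used, and a difference in RNA processing between the groups was not tested.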

How the results depend on the processing

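The clusterings, the minimum of 3070 UMIs, the removal of cells rich in globin or Igkc and the doublet scores were alternatives chosen after seeing the data. No paired analysis was possible because the cells carry no replicate number. For the same reason the tests, the leave-one-out settings and the other models planned were not run. HSC-like cells with a UMI of an HSC marker and no UMI of the most abundant markers of other lineages numbered 0. Drawing equal cell numbers over all cells moved nothing, so neither setting gave a value. Depth and free RNA limit genes with few UMIs. Of 1459 alternative log2 folds in HSC-like cells 25 reversed, of 959 over all cells 8, and in the other classes 0, where the other clusterings were run for genes in monocyte progenitor-like cells alone. With the same class composition 113 folds over all cells left their intervals, 3 reversed and only 21 held. In HSC-like cells 70, 12 and 51 did with each group clustered alone, and 64, 6 and 61 with clusters of centred values. Of 373 list medians in HSC-like cells 4 reversed, of 259 over all cells 1 and of 338 in monocyte progenitor-like cells 4, and of 53 ratios of shares 2. The cause was not tested for any value below, except where cells rich in globin were removed.

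With each group clustered alone, the ratios of shares were 0.611 for monocyte progenitor-like, 2.01 for HSC-like, 2.17 for megakaryocyte-like, 0.0816 for erythroid-like, 0.953 (0.840 to 1.08), within counting error, for neutrophil progenitor-like and 9.58 for lymphoid-primed-like cells. The lymphoid-primed-like, HSC-like, erythroid-like and megakaryocyte-like ratios depended on the naming rule. The 9.58 rested on 52 control cells, while 546 control cells in a cluster with its highest enrichment, 1.23, for lymphoid-primed markers stayed unnamed. The 2.01 rested on a control cluster with HSC and multipotent enrichments of 0.7314 and 0.7306, while the same 546 control cells and 649 cells of the B-ALL environment, with HSC enrichments of 1.18 and 1.09, stayed unnamed. Of the control monocyte progenitor-like cells 707 lay in a cluster at 0.633 led by histone genes, and of the megakaryocyte-like cells of the B-ALL environment 553 lay in a cluster at 0.571, near the bound of 0.5. The r between classes was 0.203. In monocyte progenitor-like cells the medians of lymphoid-primed markers, basophil and mast cell markers and emergency granulopoiesis were -0.22, 0.94 and 0.052, and those of S phase genes, G2/M genes and glycolysis, at 0.07, 0.05 and 0.12, came to lie within the random range. In HSC-like cells the log2 folds were -1.37 for Hba-a2, -1.40 for Hba-a1, -0.95 for Hbb-bs, 0.85 for Ifi27l2a, -0.39 for Hsph1, 0.998 for Kif2c, -0.57 for Rrp1b, -0.14 for Nop16, -0.044 for Acat2, -0.16 for Prdx1, -0.085 for Cdkn1a and 0.13 for Gadd45a.

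With clusters of centred values, the ratios were 0.790 for monocyte progenitor-like, 8.75 for HSC-like and 0.189 for erythroid-like cells. They were 0.765 (0.656 to 0.890), beyond counting error, for lymphoid-primed-like and 1.10 for basophil and mast cell-like cells, the last reversed. The reversal came from a cluster at an enrichment of 0.661, led by mitotic genes and without a basophil marker among its leading genes, with 146 control and 242 B-ALL environment cells. The cluster led by Ms4a2 and Gzmb, at 3.14, held 178 and 115 cells and did not reverse. The r was 0.411. In HSC-like cells 5 pathway lists lay above and 2 below the random range, and the medians of immediate early genes, S phase genes and quiescence genes reversed to -0.10, 0.23 and -0.069. The p53 median in monocyte progenitor-like cells was -0.00593, and in those cells TNF and NF-kB response, S phase genes, glycolysis, unfolded protein response and basophil and mast cell markers, at 0.07, 0.05, 0.06, 0.12 and -0.36, came to lie within the random range. In HSC-like cells Tcf4 was at -0.044, Dscc1 at 0.18, Cdc6 at 0.10, Tyms at 0.15, Ltbp3 at -0.18 and Ptprc at -0.065. With finer clusters of the map r was 0.451 and the erythroid marker median in HSC-like cells 0.098.

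Among cells with at least the median UMIs of the shallower group, the ratios were 4.77 for megakaryocyte-like and 1.16 (0.9504 to 1.42), within counting error, for multipotent progenitor-like cells. They were 1.07 for lymphoid-primed-like and 1.02 (0.696 to 1.51) for basophil and mast cell-like cells. The last reversed, but also lay within counting error. The lymphoid-primed-like ratio, also above 1 with each group clustered alone, was not counted as reversed, because its difference had been within counting error. With the same class composition, multipotent progenitor markers were at -0.024 over all cells, Adgrg1 at -0.18, Ifi44 at -0.097 and Mt2 at 0.0016. Without cells rich in globin or Igkc, Hba-a2, Hba-a1, Hbb-bs and Ighm were at -0.84, -0.57, -1.03 and -0.52 over all cells, and Hba-a2, Hba-a1 and Hbb-bs at -0.072, -0.83 and -0.81 in HSC-like cells, so these globin folds rested on the removed cells. Without the highest doublet scores Ighm was at -0.50 over all cells. In HSC-like cells Hba-a1 and Hbb-bs were at -2.26 and -1.78 with the same number of cells from each group, and at -1.55 and -0.90 among cells of middle depth.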

Other observations

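Tcrg-C1, a constant gene of the T-cell receptor gamma chain, was found in most erythroid-like cells of the B-ALL environment. A UMI of Tcrg-C1 was present in 158 of those 203 cells (77.8%) and in 11 of 848 control erythroid-like cells (1.30%). In the B-ALL environment 6.93% of megakaryocyte-like cells and 0.806% of HSC-like cells had a UMI, and median UMIs per cell were 14321, 12752 and 7293 in these classes. In T and NK cell-like cells, a UMI was found in 14 of 21 control cells and 3 of 32 cells of the B-ALL environment.

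Several genes had the same direction in every class in which they were tested. Slfn2, a Schlafen gene, and Tnip3 were higher in the B-ALL environment in all 8 classes, with log2 folds from 0.70 to 4.98 and from 0.54 to 5.57. S100a4 was higher in all 7 classes tested, and Enah in all 5. Ccnd1, the cyclin D1 gene, was lower in all 8 classes, with log2 folds from -4.31 to -1.22. The nuclear long RNAs Malat1 and Neat1 were lower in all 8, from -0.97 to -0.15 and from -1.60 to -0.80. Tsix, which lies antisense to Xist, was lower in all 8, from -2.31 to -1.69, and its reads cannot be assigned with certainty because strand handling was not given in the sources used. These genes were chosen after their values were seen.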
